A study of Homo sapiens with 22 samples.

How the data were processed

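The study used DLD-1 cells, an established human colorectal adenocarcinoma line, in which MTBP carried an auxin-inducible degron tag (mAID) on some copies and a FLAG epitope on others. MTBP is the partner of Treslin, and both proteins are needed to start DNA replication. The 22 libraries fall into 8 groups. CUT&RUN, in which an antibody directs a nuclease to cut out the DNA around its target, was done with a FLAG antibody in cells with full-length MTBP-FLAG (WT, 3 libraries), in cells with MTBP-deltaC-FLAG (3 libraries) and in an untagged control (3 libraries), and with IgG (2 libraries) and an antibody to H3K4me2 (2 libraries). EdU-seq, which labels newly made DNA with a nucleotide analogue and sequences it, was done in WT cells held in G1, in released WT cells and in released deltaC cells (3 libraries each). EdU was given at 10 µM for 3 hr, DNA was sheared to 300 to 500 bp, and the label was linked to biotin with 100 µM biotin azide, per the labels' protocols.

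The 3 deposited lists are the MTBP peaks, the initiation zones from EdU-seq and the H3K4me2 peaks. Per the submitters' processing notes, the tools were Trim Galore, Bowtie2, MACS2 and HOMER, and the build was hg38. Versions, parameters and the order of steps are not given in the sources used here, nor is whether replicates were pooled before peaks were called, or which EdU-seq libraries the zones came from. In the MTBP list, the authors gave each peak a score of unstated scale, and a signal value for the WT line and for the deltaC line. Each signal value is the authors' value for the line, with no library values beside it and an unstated scaling. The signal is never negative and has exact zeros, 2 for WT and 188 for deltaC. The names of the deposited MTBP peaks begin with WT or deltaC, so peaks named for each line stand in 1 list. The authors' list also gives a signed distance in bp to the nearest start site, a summit position, an annotation and a location class (promoter, enhancer or super-enhancer, others). In the zone list, the authors gave the average score of the peaks in each zone. In the H3K4me2 list, the authors' values per peak were a score, a fold enrichment over background, a −log10 p-value and a −log10 q-value, and a summit offset in bp. All scores, folds and signals are the authors' own, and served to describe, rank or filter peaks within a list. The depth of the libraries is unknown from these lists, so no counting error was computed.

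The planned count model for WT against deltaC needed library values, so these were compared as the authors' pooled values, log2((deltaC + 1)/(WT + 1)), without a p-value. The planned comparison of EdU signal between WT and deltaC was not run, because the zone list has no values per line. The G1-arrested EdU-seq, IgG and untagged libraries were not analysed here. No per-sample column was left unused. Peaks on Y were left out of all comparisons (10 MTBP and 116 H3K4me2 peaks), which leaves chromosomes 1 to 22 and X. The span of each chromosome was its largest coordinate in any list or in the gene table, 3030 Mb in all.

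Lists were compared by overlap of at least 1 bp. Each observed share was set against 1000 random rotations of the list along its chromosomes, which keep the spacing of the features, with a 2-sided permutation p, of which 0.000999 is the smallest that 1000 draws can give. A difference between shares got a p from the same rotations and a 95% interval from a bootstrap of 5-Mb blocks (1000 draws). A difference was called only where p was below 0.05 and the interval left out 0. The joint model was a logistic regression of 100-kb bins, with a bin counted as in a zone where a share over 0.5 of it was covered, on log2(number + 1) of MTBP peaks, H3K4me2 peaks and gene ends, each per SD, with intervals from 300 block bootstraps. A planned GC term was left out, since no genome sequence was used here. Intervals of medians came from 500 block bootstraps. A group's median deltaC/WT was given its percentile among 10000 random lists of the same size matched on mean signal in 20 strata. The random lists drew single peaks from the whole genome, so the percentiles take no account of the clustering of peaks.

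Genes came from RefSeq's table for GRCh38.p14, the assembly of hg38. That table was used without strand, so either end of a gene stood in for its start site, and a gene counted as having a peak where any part of the peak lay within 1 kb of either end. For the share of peaks near genes, the peak centre had to lie within 1 kb of an end of any annotated gene. It counted as in a zone where an end lay inside. The 12 gene lists were published replication origin loci (13 genes), initiation factors (48), genes at common fragile sites (22), replicative histones (68), ribosomal proteins (84), olfactory receptors (392), HOX genes (39), numbered zinc finger (ZNF) genes (509), colorectal epithelium (28), Wnt targets (19), housekeeping genes (15) and markers of hepatocytes, neurons, blood and muscle (48). All their members were found among the 19974 protein-coding genes. Each list was compared with all other protein-coding genes for MTBP, H3K4me2 and zones by Fisher's exact test (2-sided), with Benjamini-Hochberg adjustment over the 36 tests. MTBP was also compared among genes with H3K4me2 alone, by the same test, adjusted over the 12 lists. Every adjusted p of a gene list is of that test.

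The genes and regions named were fixed by rule: all origin loci, the first 4 members of every other list and up to 3 members that differed from the list's majority for MTBP, the nearest protein-coding genes of the 10 MTBP peaks with the highest score and of the 5 with the lowest, and the 5 widest zones, the 5 zones of at least 50 kb with the most MTBP peaks per Mb and the 5 widest zones without MTBP, with up to 6 genes each. Some of the genes and regions that this rule takes are not reported here. The gene lists, this rule, the main tests and most alternatives were chosen before the data were examined. The comparisons by location class, by distance from a zone, by decile of H3K4me2 fold, by quintile of zone score and of MTBP among genes with H3K4me2 were chosen after the data had been seen, as were those of deltaC over WT other than its overall level.

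Alternatives tried were a 50% overlap, uniform placement, autosomes only, stricter peaks (score at or above the median), H3K4me2 peaks merged within 1 kb, zones widened by 50 kb or of at least the median width, peaks shared within 500 bp, peaks farther than 5 kb from a gene end, 50-kb bins, other forms of the bin model, deciles of the score, WT signal or width for peak strength, other parts of the zone, and for genes a 5-kb window, zones within 50 kb, 1 gene per 500-kb cluster, and start sites placed by the authors' distances. Differences within strata (300 block bootstraps) used deciles of H3K4me2 fold, 20 strata of mean signal and quintiles of the number of protein-coding genes within 500 kb. Windows of 500 kb with at least 8 peaks were ranked by median deltaC/WT, and the lowest was set against 1000 permutations of the ratios within 20 strata of WT signal or of genes nearby.

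The methods were tested on simulated data. Of 40 lists unrelated to the zones, 2 had p below 0.05, and 3 of 3 planted lists were recovered. Of 40 planted differences in zone share, 40 intervals covered the planted value. With strata, 19 of 20 intervals covered 0 where only strength was shared, and 18 of 20 covered a planted difference. The largest error of a term of the bin model was 0.0482. Of 40 unshifted gene lists, simulated with independent values and so without clustering, 1 fell in the outer 5 percent of its random lists. Of 200 simulated gene lists, 197 were recovered. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.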

Results

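MTBP binding was mapped by CUT&RUN in DLD-1 cells, a human colorectal adenocarcinoma line, and sites of replication initiation by EdU-seq of cells entering S phase. MTBP works with Treslin at the step where the replicative helicase is loaded with CDC45 and GINS. Of the 29858 MTBP peaks in the list, 29848 lay on chromosomes 1 to 22 and X, with a median width of 937 bp and 31.8 Mb covered. The 2473 initiation zones had a median width of 48321 bp, from 6302 to 420428 bp, and covered 143 Mb or 4.72% of the 3030 Mb spanned. The 62388 H3K4me2 peaks, a mark of active promoters and enhancers, had a median width of 1408 bp. The authors' MTBP score ranged from 33 to 2665 (median 190), and the median H3K4me2 fold enrichment was 14.4. There were no replicate values in any list, so the errors given are intervals over the genome. They do not measure the spread between cultures.

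The first question was where MTBP lay relative to H3K4me2. MTBP peaks were almost all at H3K4me2. Of the MTBP peaks, 29519 (98.9%) overlapped an H3K4me2 peak, against 6.04% when the list was rotated along the chromosomes, a 16.4-fold excess (permutation p = 0.000999, the smallest that 1000 rotations can give). The excess was 26.4-fold when at least 50% of the peak had to be covered. In the other direction, 43.6% of H3K4me2 peaks had MTBP. H3K4me2 peaks with MTBP were stronger and wider, with a median fold enrichment of 23.0 and width of 2189 bp, against 9.35 and 973 bp without MTBP. From the lowest to the highest decile of H3K4me2 fold, the share with MTBP went from 4.75% to 84.6%. The untagged and IgG libraries were not analysed here, so how far background signal at active promoters and enhancers adds to this overlap was not tested.

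The 10 MTBP peaks with the highest scores all overlapped H3K4me2. By the authors' classes 5 of them were at promoters and 4 at enhancers. The highest score (2665) belonged to an intergenic peak at 2:62303783-62307966 of the enhancer class, 81143 bp from B3GNT2, the nearest protein-coding gene. The next was annotated to a promoter and lay 110 bp from PPM1B (2:44167423-44170108, score 2336), a protein phosphatase gene. The third lay in an enhancer-class intron annotation 83827 bp from ATL2 (2:38461642-38463180, score 2210). The rest included promoter-annotated peaks whose nearest protein-coding genes were PPFIBP2, TMEM53, NRL and PAIP2B. The annotated promoters were not matched to these genes. An exon peak in FANCL, a Fanconi anaemia ubiquitin ligase gene, and 2 intronic peaks in TBCD, a tubulin cofactor gene, completed the 10. The peaks near B3GNT2, PPM1B, ATL2, FANCL and PAIP2B all lay on chromosome 2, between 38461642 and 71227909. The copy number of these regions was not examined here, and it could affect the ranking by score. Of the 10 peaks, 3 were in an initiation zone, those near ATL2, TMEM53 and NRL. Of the 5 peaks with the lowest scores (33 to 40), 4 were centred in TATDN1, IMMP2L, SART3 and NDC80, and the other was intergenic, 48907 bp from BDNF, the nearest protein-coding gene. Of these 5, 4 overlapped H3K4me2 and 0 were in a zone.

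MTBP peaks were also frequent at genes. Within 1 kb of a gene end lay 30.2% of them, against 6.53% in rotations (4.62-fold, permutation p = 0.000999). By the authors' own distances, 8986 peaks (30.1%) were within 1 kb of a start site and 42.8% were more than 10 kb away, and the median distance was 6767 bp. The excess was 2.03-fold within 5 kb (48.9% of peaks), and 9.04-fold within 1 kb of protein-coding genes alone (23.8% of peaks).

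The second question was whether MTBP lay in the initiation zones, where EdU-seq placed the start of replication. EdU was given for 3 hr and the cells were entering S phase, so initiation later in S phase may be missing from the zones. Initiation zones held 47.9 MTBP peaks per Mb, against 7.96 per Mb outside them. Of the MTBP peaks, 6860 (23.0%) were in a zone, against 5.70% in rotations (4.03-fold, permutation p = 0.000999). Of the zones, 2023 (81.8%) had at least 1 MTBP peak, against 32.0% in rotations (2.55-fold, permutation p = 0.000999). H3K4me2 was enriched there too, with 11011 peaks (17.6%) in zones against 5.50% (3.21-fold, permutation p = 0.000999), or 76.9 per Mb in zones and 17.8 outside. MTBP density fell off with distance, from 47.2 per Mb among peaks centred in zones to 30.3 within 10 kb of them and 4.39 more than 1000 kb away. The number of MTBP peaks per 100 H3K4me2 peaks went from 63.1 in zones to 38.8 at the farthest distance.

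**Figure D1:**
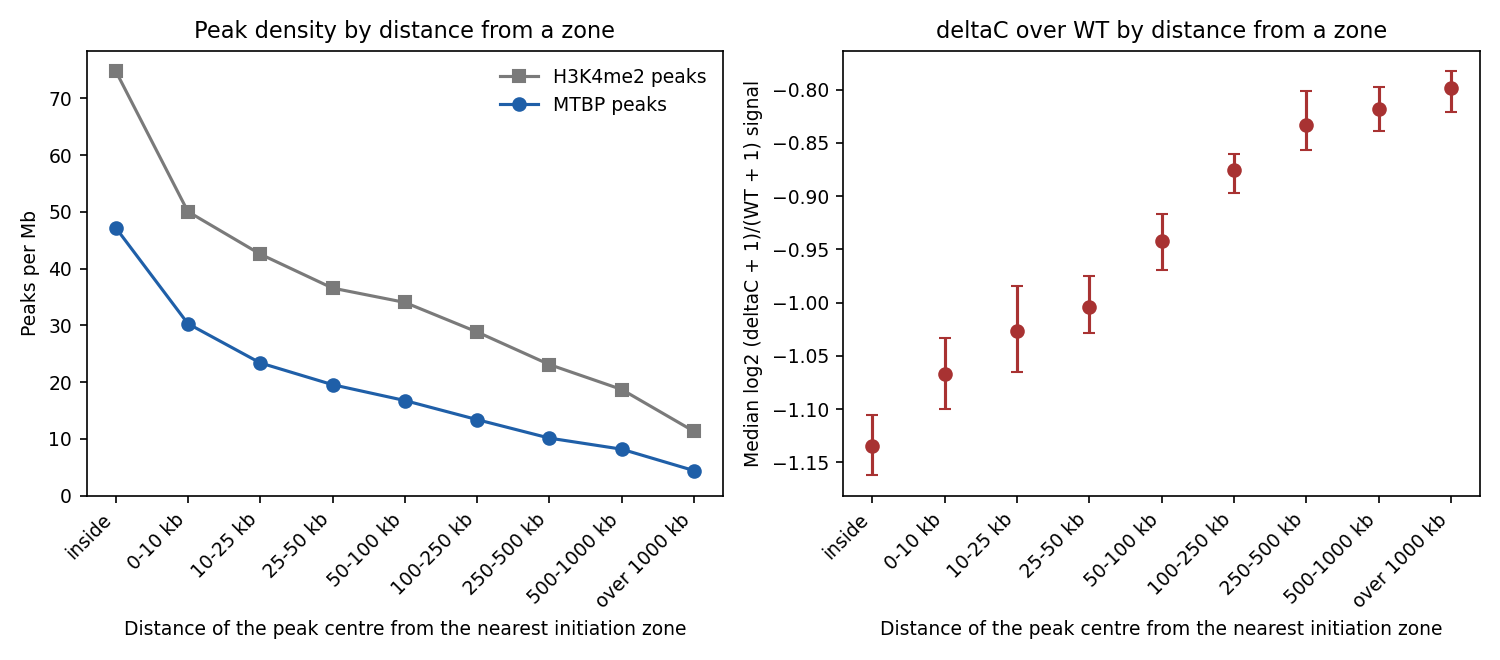
Left, MTBP and H3K4me2 peaks per Mb by distance of the peak centre from the nearest initiation zone; MTBP went from 47.2 per Mb inside to 4.39 beyond 1000 kb. Right, the median log2 ratio of the authors' deltaC signal over their WT signal in the same distance groups, with 95% block bootstrap intervals; it went from −1.13 inside to −0.80 beyond 1000 kb.

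Zones with higher scores more often had MTBP. From the lowest to the highest quintile of the authors' zone score, the share with an MTBP peak was 50.2%, 76.4%, 87.9%, 95.2% and 99.4%. The lowest quintile had a median width of 14.6 kb and the highest 94.99 kb, and MTBP per Mb was 41.6 and 54.4. Across zones, which are not independent replicates, the number of MTBP peaks went with the score (rho 0.69) and width went with it more closely (rho 0.89), while MTBP per Mb did so weakly (rho 0.21). Among zones of like width, those of higher score held more MTBP peaks in 10 of 10 width deciles, by 1.03 peaks on average.

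The 5 widest zones held 15 to 24 MTBP peaks each. The widest (6:43662969-44083397, 420 kb) contains VEGFA, the vascular growth factor gene, with RSPH9 and MRPS18A, and held 20 MTBP and 32 H3K4me2 peaks. The others held BAZ1B, BCL7B and MLXIPL (7:73520999-73882688, 19 MTBP peaks), ADAM15 and EFNA4 (1:155005796-155325769, 19), PTPN1, a tyrosine phosphatase gene (20:50216558-50534684, 15), and ERRFI1, a feedback inhibitor of EGFR (1:8021541-8337538, 24). The 5 densest zones of at least 50 kb held 151 to 155 MTBP peaks per Mb. They include zones with no protein-coding gene end (4:74624786-74695712 and 18:3587938-3673680), the AMOTL2 zone (3:134282879-134368412), the zone of the cytokine genes LIF and OSM (22:30169223-30288711, 18 MTBP peaks) and the METRNL zone (17:83049001-83121611, 11 MTBP peaks).

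There were 450 zones with no MTBP peak, with a median width of 21.2 kb against 55.2 kb for the rest. H3K4me2 was present in 276 of them, and 174 had neither. The 5 widest were 87.6 to 115 kb wide and held 3 to 6 H3K4me2 peaks each. They include the zones of ABR (17:1193226-1308725), LDB3 and OPN4 (10:86629401-86734559), PGF (14:74907317-75000068) and KCNJ4 and DDX17 (22:38395981-38483617).

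The next comparison set H3K4me2 peaks with MTBP against those without. Of the 27182 H3K4me2 peaks with MTBP, 22.7% were in an initiation zone, against 13.8% of the 35206 without, a difference of 8.91 percentage points (95% interval 8.05 to 9.68, permutation p = 0.000999). In the lowest decile of H3K4me2 fold the shares were 23.0% and 11.5%, and in the highest decile 23.5% and 19.5%. The difference was 5.22 points among H3K4me2 peaks of at least the median score, 5.80 within deciles of H3K4me2 fold, and 5.67 with fold, gene ends and gene density held alike. Of the 329 MTBP peaks without H3K4me2, 27.7% were in zones, against 22.9% of those with it. That difference of −4.73 points did not pass (interval −10.8 to 0.950, permutation p = 0.0569). It turned to 0.617 points when only H3K4me2 peaks of at least the median score counted, and passed at −8.46 points with zones widened by 50 kb and at −7.22 points for zones of at least the median width.

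MTBP, H3K4me2 and genes were then set against zones together, in bins of 100 kb. The log odds of a bin being in a zone went up by 0.61 per SD of MTBP peaks (95% interval 0.51 to 0.74), by 1.63 per SD of H3K4me2 peaks (1.47 to 1.80) and by 0.69 per SD of gene ends (0.60 to 0.78). Of the bins, 1204 were in zones and 29104 were not. With MTBP alone in the model its term was 1.63.

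Among MTBP peaks, those of the authors' enhancer class were in zones most often. The share was 34.5% of 5257 enhancer peaks, 27.3% of 10363 promoter peaks and 15.6% of 14228 others. The differences were 18.96 points between enhancer and other peaks (interval 16.4 to 21.5), 11.7 between promoter and other peaks (9.64 to 13.8) and 7.27 between enhancer and promoter peaks (5.12 to 9.17). By score, 25.8% of the highest quartile and 21.2% of the lowest were in zones, a difference of 4.51 points (3.13 to 5.95, permutation p = 0.000999). The difference was 8.95 points between the highest and lowest deciles, and 10.8 points between the widest and narrowest quartiles, a comparison chosen after the data had been seen. Inside zones, MTBP peaks showed no preference for the edges: 39.96% lay in the outer 20% at either end, against 40.02% expected from random places in the same zones (permutation p = 0.916). For H3K4me2 peaks it was 39.4% (permutation p = 0.226).

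**Figure D2:**
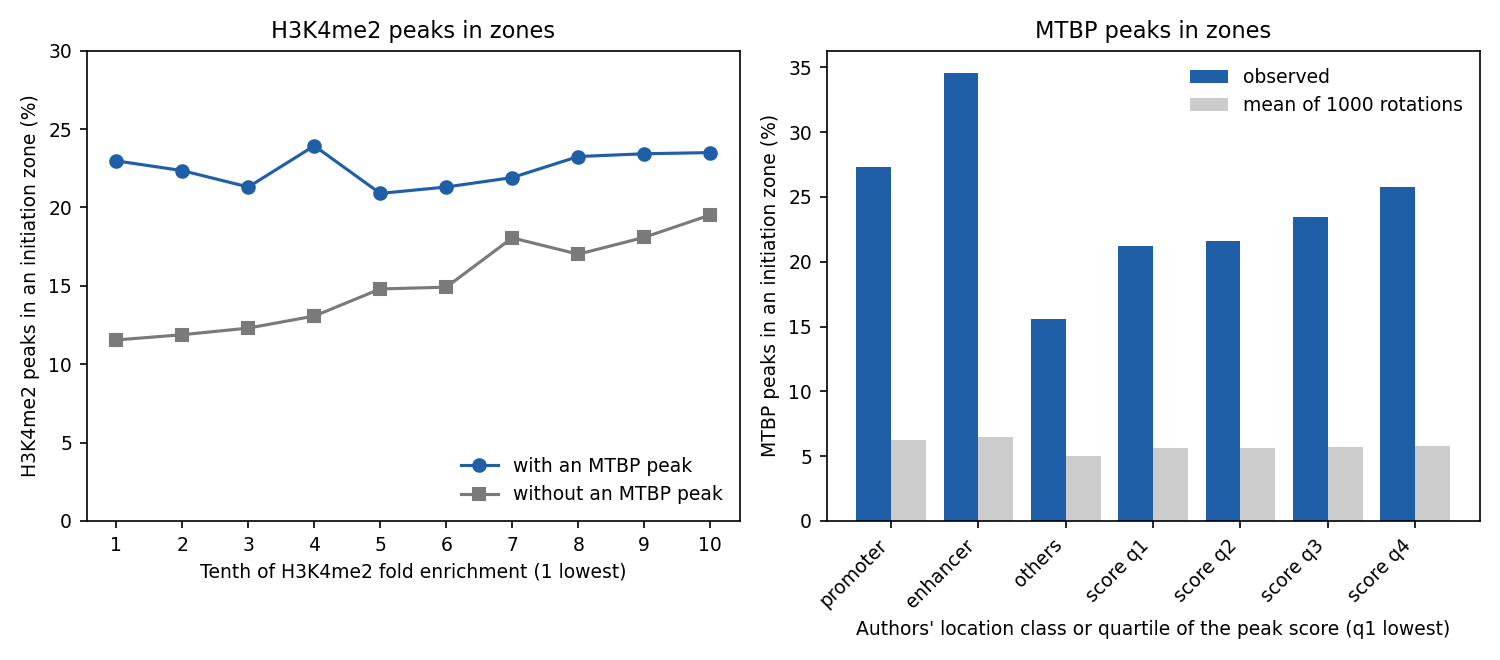
Left, the share of H3K4me2 peaks in an initiation zone by decile of H3K4me2 fold enrichment, with and without an MTBP peak; it was 23.0% and 11.5% in the lowest decile, and 23.5% and 19.5% in the highest. Right, the share of MTBP peaks in a zone by the authors' location class and by quartile of peak score (bars, observed; grey, mean of 1000 rotations); it was 34.5% for enhancer, 27.3% for promoter and 15.6% for other peaks.

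The fixed gene lists show which loci carried MTBP. Of all 19974 protein-coding genes, 42.8% had an MTBP peak, 64.3% an H3K4me2 peak and 23.8% an end in a zone. Of the 36 tests, 21 had an adjusted p below 0.05 (Fisher's exact test with Benjamini-Hochberg adjustment). MTBP was also compared among genes with H3K4me2 alone, where 66.4% to 66.7% of the genes outside a list had it. Of the 12 lists, olfactory receptors (2 of 16, adjusted p = 0.000154) and ZNF genes (178 of 308, 57.8%, adjusted p = 0.00876) then had fewer genes with MTBP by Fisher's exact test, and the other 10 lists did not pass.

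Of the 13 genes at published origin loci, 10 had MTBP (76.9%, adjusted p = 0.038 by Fisher's exact test), 12 had H3K4me2 (adjusted p = 0.0669) and 4 were in a zone (adjusted p = 0.605). Genes that share a locus were counted separately, and MCM4 and PRKDC had the same MTBP peak. With this list and the other genes thinned to 1 per 500-kb cluster, which left 3.70% of the other genes in zones, the H3K4me2 test (exact adjusted p = 0.0243) and the zone test (23.6 points, 0.0134) passed. The MTBP call was lost among genes with H3K4me2 (10 of 12, exact adjusted p = 0.615), with a 5-kb window (adjusted p = 0.12), with 1 gene per 500-kb cluster against all other genes (0.129) and with start sites placed by the authors' distances (0.148). The list holds genes, and the mapped positions of the origins within these loci were not used here. The MCM4 and PRKDC locus had a peak between the divergent genes (8:47959839-47961713), centred 165 bp from MCM4, which encodes a helicase subunit. At the LMNB2 and TIMM13 locus, a peak was centred 194 bp from TIMM13 (19:2427347-2428213). It spans the gap between the genes and reaches the lower-coordinate end of LMNB2 (2428166). Another peak was centred 137 bp from the higher-coordinate end of LMNB2 (19:2456670-2457522). LMNB2 had its higher-coordinate end in a 204-kb zone, which starts at 19:2438633, and TIMM13 had no end in a zone. MYC had a peak at its higher-coordinate end (8:127742569-127743518) and no zone. TOP1 (20:41027844-41028834), DNMT1 (19:10194486-10195401) and HSPA4 (5:133050627-133053210) had both a peak and a zone. HBB, a globin gene, had neither MTBP nor H3K4me2, and its nearest MTBP peak was centred 46194 bp away. HPRT1 and FMR1 had H3K4me2 and no MTBP. Both lie on X, where 15.6% of H3K4me2 peaks had MTBP, against 44.3% on the autosomes.

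Of the 48 initiation factor genes, 38 had MTBP (79.2%, adjusted p = 1.77e-06) and 47 had H3K4me2 (97.9%, adjusted p = 1.16e-07), while 27.1% were in a zone (adjusted p = 0.647), all by Fisher's exact test. The zone test passed with this list and the other genes thinned to 1 per cluster (21.8 points, exact adjusted p = 1.28e-06) and did not when all other genes were kept (0.827). Among genes with H3K4me2 the MTBP call was lost, with 80.9% of these genes against 66.4% of others (exact adjusted p = 0.172). MTBP itself had a peak (8:120444902-120445861) centred 38 bp from its gene end, and TICRR, which encodes Treslin, had a peak at 15:89574978-89575811. TOPBP1 and CDC45 also had MTBP. GINS3, RECQL4 and DONSON had H3K4me2 and no MTBP within 1 kb. The housekeeping genes had MTBP at 12 of 15 (80.0%, adjusted p = 0.0133 by Fisher's exact test) and H3K4me2 at 15 of 15 (adjusted p = 0.00491), with ACTB, GAPDH and TBP among those with both and POLR2A among those without MTBP. Zones held 2 of the 15 (exact adjusted p = 0.605), and the difference turned to 15.3 points with zones within 50 kb (exact adjusted p = 0.344) and to 9.63 points with list and other genes thinned (0.164). The MTBP call was lost among genes with H3K4me2 (exact adjusted p = 0.618) and with MTBP peaks of at least the median score (exact adjusted p = 0.104).

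Of the 84 ribosomal protein genes, 56 had MTBP (66.7%, adjusted p = 3.93e-05), 82 had H3K4me2 (97.6%, adjusted p = 8.64e-13) and 29 were in a zone (34.5%, adjusted p = 0.0485), by Fisher's exact test. RPL10, which lies on X, had MTBP and a zone, whereas RPL11, RPL14 and RPL24 had H3K4me2 and neither of the others. Among genes with H3K4me2, 68.3% of ribosomal protein genes and 66.4% of others had MTBP, and the call was lost (adjusted p = 0.889), as it was with peaks of at least the median score (exact adjusted p = 0.108). The zone call was lost with 1 gene per 500-kb cluster against all other genes (adjusted p = 0.163) and, through the adjustment alone, with stricter MTBP peaks (0.0509) and the authors' distances (0.0536).

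Genes of the colorectal epithelium were in zones more often than other genes. Of the 28, 17 had an end in a zone (60.7%, adjusted p = 0.000102 by Fisher's exact test), while 15 had MTBP within 1 kb (53.6%, adjusted p = 0.344) and 20 had H3K4me2 (adjusted p = 0.605). EPCAM, an epithelial adhesion gene, lay in a 231-kb zone (2:47161421-47391992) whose score of 10226 was the highest in the list, and had an MTBP peak (2:47368728-47370645). The copy number of this region was not examined here. CDX2, an intestinal transcription factor gene, had MTBP and a zone. VIL1, CDH1, CDH17 and GPA33 were in zones with no MTBP within 1 kb of an end, the nearest peaks being centred 4052 to 7254 bp away, and CDX1 had H3K4me2 with neither. With a 5-kb window, 21 of the 28 had MTBP and the test passed (exact adjusted p = 0.0353). With start sites placed by the authors' distances the difference in MTBP turned to −10.7 points (adjusted p = 0.351). Wnt target genes had H3K4me2 at 18 of 19 (adjusted p = 0.0083 by Fisher's exact test), MTBP at 12 (63.2%, adjusted p = 0.147) and a zone at 7 (36.8%, adjusted p = 0.255). With MTBP peaks of at least the median score, 10 of the 19 had MTBP (52.6%, against 24.5% of other genes) and the test passed (exact adjusted p = 0.025). With list and other genes thinned to 1 per cluster the tests of MTBP (exact adjusted p = 0.044) and zones (33.1 points, 1.63e-05) passed, and with all other genes kept they did not (0.184 and 0.301). AXIN2, a Wnt feedback inhibitor, had MTBP (17:65560345-65562466, score 800) and a 245-kb zone. LGR5 and ASCL2, stem cell genes, had MTBP and no zone, and NOTUM and TCF7 were in zones without MTBP within 1 kb.

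Several groups were rare in zones. That does not show that replication never starts near them, since initiation later in S phase may be missing from the zones. Genes at common fragile sites, long genes prone to breakage, had an end in a zone at 0 of 22 (adjusted p = 0.00919 by Fisher's exact test), MTBP at 10 (45.5%, adjusted p = 0.856) and H3K4me2 at 12 (adjusted p = 0.467). FHIT and WWOX had MTBP at an end, and LRP1B had none. The zone call was lost when the list and the other genes were thinned to 1 per 500-kb cluster, which left zones at 3.73% of the other genes. Replicative histone genes had MTBP at 30 of 68 (44.1%, adjusted p = 0.902), H3K4me2 at 54 (79.4%, adjusted p = 0.0201) and a zone at 0 (adjusted p = 7.14e-08), by Fisher's exact test. Among genes with H3K4me2 their MTBP share was 55.6%, below that of other genes (exact adjusted p = 0.333). These genes sit in few clusters: 1 gene per cluster left 6 genes, with which the zone call (exact adjusted p = 0.541) and the H3K4me2 call (0.575) were lost against all other genes. H1-2, H1-3, H1-4 and H2AC11 had MTBP, and H1-1 did not.

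HOX genes had MTBP at 19 of 39 (48.7%, adjusted p = 0.605), H3K4me2 at 31 (79.5%, adjusted p = 0.1) and a zone at 2 (5.13%, adjusted p = 0.00889), by Fisher's exact test. With 1 gene per cluster only 4 HOX genes remained, 1 of them in a zone, and the zone difference turned to 1.12 points against all other genes. The direction for MTBP turned with that setting (−17.8 points), among genes with H3K4me2 (−5.17), with stricter MTBP peaks (−9.17) and with the authors' distances (−14.7). With a 5-kb window the share with MTBP was 71.8% (exact adjusted p = 0.0278) and that with H3K4me2 94.9% (0.00251), and with zones within 50 kb the zone call was lost (0.32). HOXA10, HOXA11 and HOXA13 had MTBP. ZNF genes had MTBP at 179 of 509 (35.2%, adjusted p = 0.00109), H3K4me2 at 308 (60.5%, adjusted p = 0.112) and a zone at 43 (8.45%, adjusted p = 7.52e-19), by Fisher's exact test. The H3K4me2 test passed with a 5-kb window, at 66.0% of ZNF genes against 73.5% of others (exact adjusted p = 0.000753). With 1 gene per cluster, 95 of 177 ZNF genes (53.7%) had MTBP, so that the difference turned to 10.7 points against all other genes (exact adjusted p = 0.0107), and that for H3K4me2 turned to 11.8 points (0.00287). The share in zones was then 14.7% (exact adjusted p = 0.00717), and it exceeded that of other genes by 10.95 points when those were thinned as well (adjusted p = 4.68e-07). With start sites placed by the authors' distances the MTBP call was lost, at 21.2% of ZNF genes against 25.03% of others (exact adjusted p = 0.0895). ZNF10, ZNF106, ZNF12, ZNF131 and ZNF133 had MTBP, and ZNF100 and ZNF101 did not.

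Olfactory receptor genes, which encode odorant receptors of the nasal epithelium, had MTBP at 2 of 392 (0.510%, adjusted p = 3.56e-91), H3K4me2 at 16 (4.08%, adjusted p = 3.4e-145) and a zone at 3 (0.765%, adjusted p = 8.08e-41), by Fisher's exact test. The 2 with MTBP were OR1F1 and OR52K1. With list and other genes thinned to 1 per cluster, the zone difference turned to 0.415 points (exact adjusted p = 0.841). Markers of hepatocytes, neurons, blood and muscle had MTBP at 6 of 48 (12.5%, adjusted p = 3.93e-05), H3K4me2 at 12 (adjusted p = 2.18e-07) and a zone at 8 (16.7%, adjusted p = 0.397), by Fisher's exact test. ALB, APOA1, APOA2 and APOB had no MTBP, and SNAP25, RBFOX3 and GRIN1 were among the 6 that had it. The MTBP call of this list was lost among genes with H3K4me2 (6 of 12, exact adjusted p = 0.562), and the H3K4me2 call with a 5-kb window (exact adjusted p = 0.075). With list and other genes thinned, the zone difference turned to 12.9 points and passed (exact adjusted p = 0.00272).

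**Figure D3:**
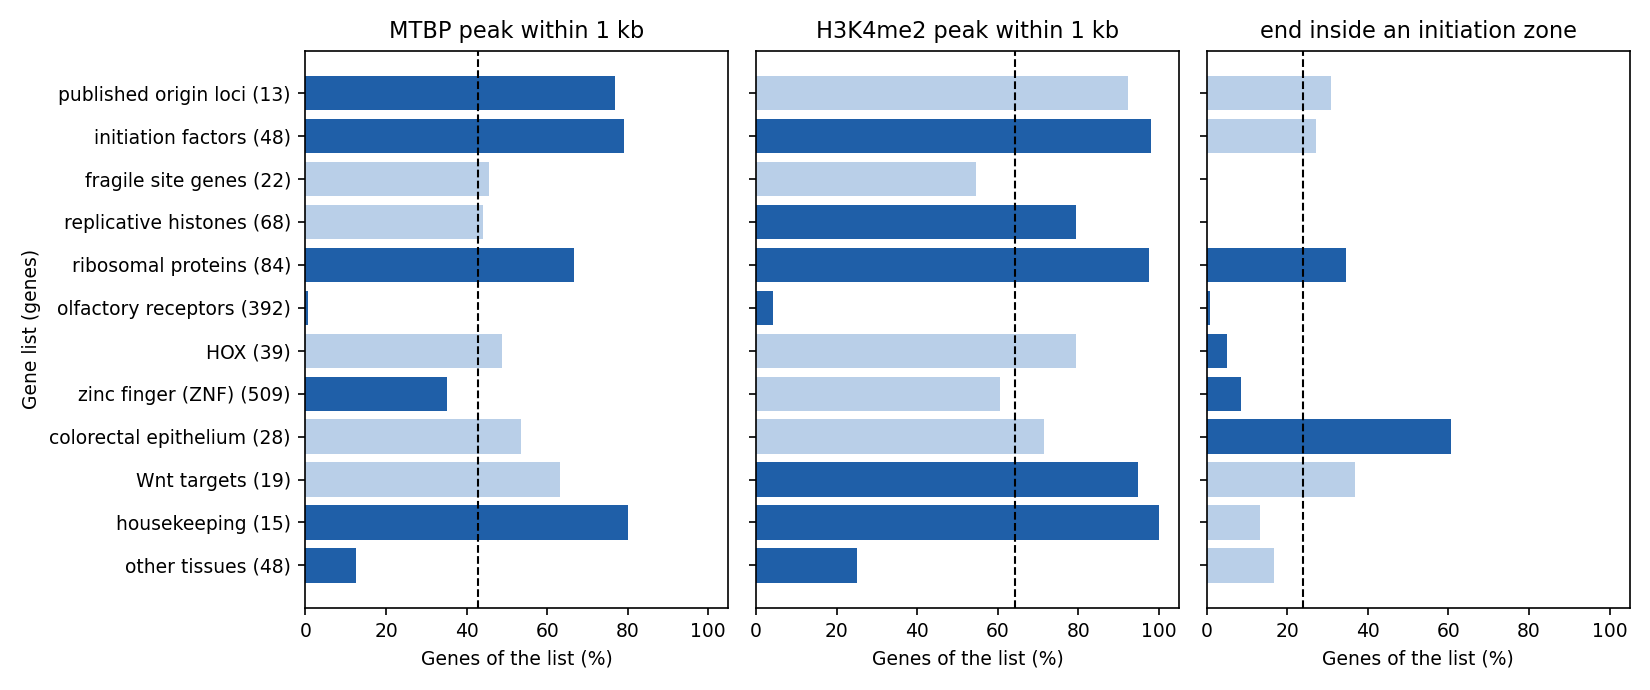
Percent of the genes of each fixed list (number of genes in brackets) with an MTBP peak or an H3K4me2 peak within 1 kb of an end, or with an end inside an initiation zone; dark bars have an adjusted p below 0.05 (Fisher's exact test with Benjamini-Hochberg adjustment), and the dashed line is the share of the other genes. Initiation factors had MTBP at 79.2%, olfactory receptors at 0.510%, and colorectal epithelium genes were in zones at 60.7%.

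The last comparison was between WT and deltaC MTBP. At 95.5% of the peaks the authors' deltaC signal was below their WT signal, at 97.6% of the 28971 peaks named for WT and 24.6% of the 877 named for deltaC. The median signal was 371 for WT and 201 for deltaC, and the median log2 ratio was −0.93, a ratio of 0.524. The ratio was lower in zones, with a median log2 of −1.14 against −0.87 outside, a difference of −0.26 (95% interval over 5-Mb blocks −0.29 to −0.23). No random list matched on mean signal had as low a median as the peaks in zones (0th percentile of 10000), though these lists ignore the clustering of peaks in zones. The ratio went from −1.13 inside zones through −1.07 within 10 kb to −0.80 beyond 1000 kb. Each line has only the authors' pooled value per peak, with unknown scaling, so the difference has no replicate check. The overall level depends on that scaling and on the naming, since most peaks were named for WT.

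The 877 peaks named for deltaC had a median log2 ratio of 0.31, which their naming may select for, though its rule is not given. Of them, 10.5% were in zones, against 23.4% of the 28971 named for WT, a difference of 12.9 points (10.6 to 15.4). Promoter and enhancer peaks had median log2 ratios of −0.97 each, and other peaks −0.88. Against random lists of like signal, which ignore clustering and had medians of −0.93, −0.92 and −0.94, these lay at the 0th, 0th and 100th percentile. Among the 10 peaks with the highest scores, deltaC signal was 14.1% to 72.1% of WT. The 2 lowest were the TBCD peaks (17:82862357-82864697 and 17:82888651-82890665), at 17.7% and 14.1%. These and METRNL lie near the end of 17q, where deltaC signal was low over a long stretch, and so does NOTUM. In the METRNL zone the median log2 ratio was −2.93 over 11 peaks, 3 of which were listed at 0 for deltaC, and in the 200 kb to either side it was −3.04 over 12 peaks. In the other 4 of the densest zones it was −0.91 to −1.22.

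**Figure D4:**
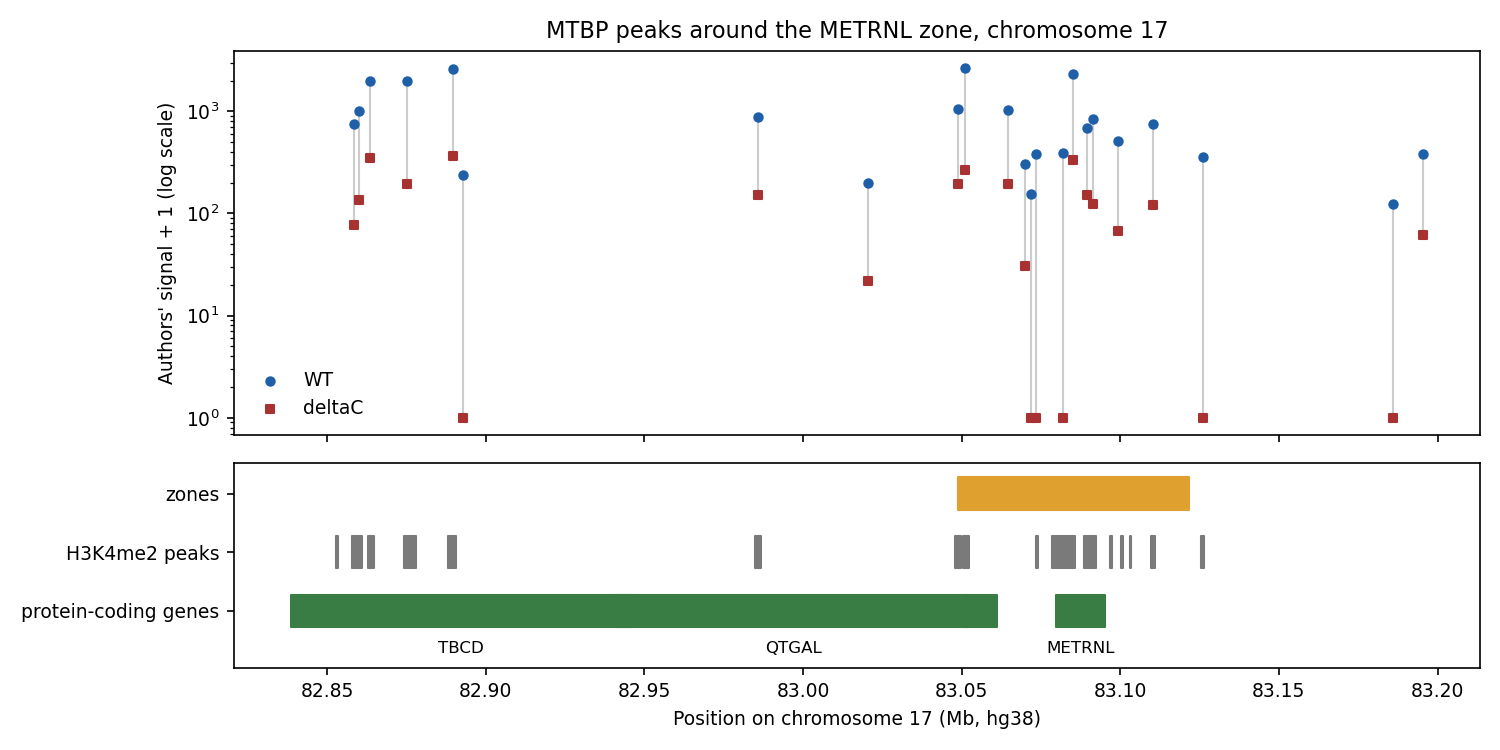
The authors' WT (circles) and deltaC (squares) signal plus 1, on a log scale, at each MTBP peak in and within 200 kb of the METRNL zone on chromosome 17 (hg38), with zones, H3K4me2 peaks and protein-coding genes below. WT signal was 155 to 2637 at the 11 peaks in the zone and deltaC signal 0 to 334, and every WT point lies above its deltaC point.

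Among the gene lists, peaks at fragile-site genes kept most deltaC signal, with a median log2 ratio of −0.37 over 11 peaks (99.9th percentile of 10000 matched random lists). At FHIT the deltaC signal was 120% of WT, at IMMP2L 77.2%, at WWOX 75.1%, at CTNNA3 66.1% and at MACROD2 52.7%. Ribosomal protein genes had the lowest percentile, with −1.22 over 69 peaks (0.14th), followed by colorectal epithelium genes at −1.28 over 18 peaks (1.77th) and Wnt targets at −1.10 over 19 (3.41st). EPCAM had 36.4% of WT signal, CDX2 31.6% and AXIN2 39.0%, while LGR5 (62.5%) and ASCL2 (68.7%) lay above the median ratio of all peaks. The other lists lay between the 8.68th and 52.4th percentiles, without olfactory receptors, whose peaks were too few to compare. The random lists were not matched on zones, in which the ratio was lower. An end lay in a zone at 0 of 22 fragile-site genes. For colorectal, Wnt target and ribosomal protein genes the share was 60.7%, 36.8% and 34.5%. The percentiles therefore do not separate a trait of these lists from their place relative to zones. Among the genes at published origin loci, deltaC signal was 49.6% to 55.1% of WT at the peaks nearest to an end of MCM4, TOP1, LMNB2, DNMT1 and HSPA4. At the TIMM13 peak, which reaches the other end of LMNB2, it was 59.2%. At MTBP it was 64.1% and at TICRR 63.0%.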

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

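Of the comparisons below, the other settings for deltaC over WT and its difference between zones and the rest, the removal of empty windows before rotation, peak width as a measure of strength, thinned lists against all other genes, genes with H3K4me2 alone, and start sites from the authors' distances were chosen only after the results had been seen. The overlaps of MTBP, H3K4me2, zones and gene ends, the difference between H3K4me2 peaks with and without MTBP, the strength comparison and the MTBP term of the bin model kept their direction and their side of the threshold under every alternative run. The shares in zones ranged from 2.93-fold to 4.22-fold over rotations for MTBP, and the difference between H3K4me2 peaks with and without MTBP from 5.22 to 11.8 points. The difference between MTBP peaks with and without H3K4me2 turned to 0.617 points with stricter H3K4me2 peaks, where 4958 peaks in place of 329 counted as without the mark, and passed at −8.46 points with zones widened by 50 kb and −7.22 points with wider zones; the cause was not tested. The outer share of zones was 40.1% with stricter MTBP peaks, just above instead of just below its random share, and passed in neither. The median log2 deltaC/WT moved to −0.97 at peaks of at least the median score and −0.95 at peaks named for WT. It turned to 0.31 at those named for deltaC, which the naming may select for, though its rule is not given. The difference in that ratio between zones and the rest moved to −0.22 at peaks of at least the median score, −0.20 in the enhancer class, −0.23 without chromosomes 17, 19 and 22, and −0.22 where both signals were at least 100; the cause was not tested. Gene list tests passed 21 times with the main settings and 17 to 23 times otherwise.

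Of the 144 list results under 7 alternatives that act on the feature tested, 88 kept their direction and side of the threshold, 19 lost and 10 gained a call, and 27 changed direction. In 84 more the alternative leaves the feature as it is and only the adjustment can move the result, which ended 2 calls. Thinning lists and other genes to 1 per 500-kb cluster left mostly isolated genes for comparison, with a zone share near 3.70%, and gave differences of 0.415 points in zones for olfactory receptors, 21.3 for HOX, 10.95 for ZNF, 9.63 for housekeeping and 12.9 for other-tissue genes, 17.5 for MTBP and 22.7 for H3K4me2 at ZNF genes, 0.771 for H3K4me2 at fragile sites, and −3.11 for MTBP at histones, −11.5 for MTBP and −3.90 for H3K4me2 at HOX genes. The same thinning gave zone calls at origin loci (23.6 points), initiation factors (21.8) and Wnt targets (33.1), which did not pass with all other genes kept. With all other genes kept, the differences that turned were −9.48 for MTBP at histones, −17.8, −14.3 and 1.12 for MTBP, H3K4me2 and zones at HOX genes, and 10.7 and 11.8 for MTBP and H3K4me2 at ZNF genes. Fragile-site genes turned for MTBP to −6.96 with a 5-kb window, −1.81 with stricter peaks and −2.21 with the authors' distances. Among genes with H3K4me2 alone, MTBP turned at histones (−10.9) and HOX genes (−5.17). Stricter peaks also turned MTBP at histones (−8.39) and HOX genes (−9.17), the authors' distances turned it at HOX (−14.7) and colorectal genes (−10.7), and zones within 50 kb turned housekeeping genes (15.3); the cause was not tested.

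No paired analysis was possible because the lists hold no library values or replicates. For that reason the other settings listed beforehand for WT against deltaC signal (DESeq2 in place of edgeR, no filter, the replicate number as a block, leaving out replicates) and those of EdU signal (the block, leaving out replicates, another pseudocount) were not run. Stricter MTBP peaks were not run for H3K4me2 in zones, where they change nothing. The depth of the libraries is unknown from the lists.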

Other observations

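The comparisons in this part were chosen only after the results had been seen, except the test of gene density for H3K4me2 peaks with and without MTBP. By the authors' annotation, 6164 MTBP peaks (20.7%) lay in a repeat. Peaks in Alu elements (788) were in zones at 32.0%, against 6.30% in rotations (5.08-fold), and those in simple repeats (148) at 34.5% (5.90-fold). Peaks in L1 elements (990) were in zones at 14.3% (2.85-fold) and those in ERVK elements (172) at 16.9% (3.42-fold). All MTBP peaks together were in zones at 23.0% (4.03-fold), below Alu and simple repeats and above L1 and ERVK. All 13 families of at least 40 peaks exceeded their rotations (permutation p = 0.000999 each, also after Benjamini-Hochberg adjustment). MTBP peaks as a whole did so too, so the excess is not particular to repeats. Whether families differed from each other or from other peaks was not tested. On X, 15.6% of H3K4me2 peaks had MTBP, against 44.3% on the autosomes, and within deciles of H3K4me2 fold the difference was −26.5 points (95% interval −29.3 to −23.6). X had a median H3K4me2 fold of 13.9, against 14.4 on the autosomes. MTBP peaks per 100 H3K4me2 peaks were 15.8 on X and 42.3 to 56.5 on each autosome.

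Peaks with hardly any deltaC signal were neighbours more often than in permutations, though most were not neighbours. Among the 299 peaks with the lowest 1% of log2 deltaC/WT (at or below −4.14), 20 pairs were adjacent, against a mean of 3.01 and at most 9 in 1000 permutations within quintiles of WT signal, and the highest 1% made 4 pairs. The 14 runs held 34 of these peaks, 32 of them with H3K4me2. They include 4 peaks around GDF6 (8:95805428-96173624), 3 at 4:29717428-30209371, 3 at 10:44393069-44753363, 3 at 15:93523406-93829881, and 2 at SLC14A2 (18:45166043-45359894), where WT signal reached 2769 and deltaC signal was listed at 0. A loss of binding and a loss of this DNA in the deltaC line cannot be told apart here. The peaks were picked for their low ratios, and copy number was not examined.

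H3K4me2 peaks with MTBP were in zones more often by 8.91 points. H3K4me2 strength as the whole cause is argued against by the difference within fold deciles, 5.80 points (4.66 to 6.95). Gene density as the whole cause is argued against by the difference within quintiles of density, 6.80 points (5.98 to 7.48), and strength, gene ends and density together left 5.67 points (4.70 to 6.68), so that strength may account for part of the gap. GC content was not tested. MTBP may mark H3K4me2 sites where replication starts, but the lists do not separate that from other properties of these sites, and no manipulation of MTBP at single sites was tested.

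The deltaC signal was lower relative to WT in zones, by −0.29 in mean log2 ratio. Differences in peak strength as the whole cause are argued against by −0.26 within strata of mean signal (−0.29 to −0.23), and gene density by −0.22 within quintiles (−0.25 to −0.19). Against the 50 kb around zones at like density the difference was −0.11 (−0.14 to −0.08), so part of the gap lies in the wider surroundings. The authors' scaling and background steps stay open, since a scaling that acts unequally on regions of high signal was not tested. A loss of binding in zones with deltaC is 1 candidate explanation, with pooled values and no replicate check.

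Over the last part of 17q (17:82506410-83196376), which holds TBCD and METRNL, the median log2 deltaC/WT of 40 peaks was −2.90, and this region held the 2 lowest of 1592 windows of 500 kb with at least 8 peaks (−3.06 and −2.88, against a median window of −0.95); the windows from 81500001 and 81000001, which include NOTUM, were at −2.03 and −1.96 and also among the lowest 5. A background of the same size at every peak and gene density were each tested with the choice of the lowest window repeated in every draw: it was at least −2.78 in 1000 permutations of the ratios among peaks of like WT signal and at least −2.78 among peaks with as many genes nearby, which argues against both as the whole cause of the lowest window (permutation p = 0.000999 each). Loss of 1 of 2 copies in the deltaC line alone, which would give a difference of −1, stays open: the region differed by −1.95 from other peaks of like WT signal (−2.36 to −1.67), but it was picked for its low values, which favours a larger difference, and the other 2 windows lay about 1 below the median window. Larger differences in copy number, or opposite ones in the WT and deltaC lines, could still account for it, as could a loss of binding, since the untagged and IgG libraries were not analysed here, and a background particular to this region was not tested. In the region 28 of 40 MTBP peaks had H3K4me2, against 98.9% of all MTBP peaks, and 9 were listed at 0 for deltaC.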
